A study of Danio rerio with 4 samples.

How the data were processed

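RNA was measured in 4 libraries of zebrafish endothelial cells, 2 from the ventral and 2 from the dorsal side of the posterior cardinal vein, at 24 hours post fertilization. Per the labels' protocols, cells expressing the photoconvertible protein Kaede were turned red by light on one side of the vein, and the red cells were sorted from 6 embryos per group. Per the labels' protocols, RNA was extracted with TRIzol together with synthetic ERCC spike-in RNAs, and libraries were made with CEL-Seq. This method tags the 3' end of each transcript with a library barcode and amplifies it by in vitro transcription. Each primer also carried a unique molecular identifier, a short random sequence that marks single molecules, per the labels' protocols. CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 and the genome build Zv9 are named in the submitters' processing notes, with no role or order.

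The deposited table holds whole-number counts per Ensembl gene and per ERCC spike-in, with 32434 gene rows, 92 ERCC rows and 5 rows that name no gene. The sources used here do not state whether counts are of reads or of distinct identifiers. No gene or spike-in exceeded 1024 counts, which is the number of distinct identifiers of 5 bases. The values were therefore read as counts of distinct identifiers with a ceiling, an inference from the values. In all 4 libraries 9 genes lay above 900 counts, among them hbae1.1, hbae1.2, hbae1.3, hbae3, hbbe3 and HBE1, and differences in these genes are compressed. The highest spike-in had 1014 and 959 counts in ventral libraries 1 and 2, and 998 and 1020 in dorsal libraries 1 and 2. Differences in the most abundant spike-ins are therefore compressed too. The rows that name no gene held 96.8% and 96.4% of the column total in ventral libraries 1 and 2, and 96.5% and 97.4% in dorsal libraries 1 and 2. They far exceed what identifier counts allow and were read as read counts. They were kept out of library sizes and tests.

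Gene names came from a table of Ensembl identifiers, which gave a symbol for 20769 of the 32434 genes and for 81.1% to 83.6% of the gene counts per library. Symbols are printed as that table gives them, so that some zebrafish genes appear in capitals. No genome of the build used by the authors was at hand, and no coordinates are given. The row for reads aligned to several places held 0 in every library, so reads shared by near-identical genes cannot be traced. Values for embryonic globins, her15.1, h3f3a and other members of multigene families are uncertain for that reason. Strand handling during counting is not given in the sources used here.

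Ventral libraries were compared with dorsal libraries with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test on the deposited counts, TMM scaling factors and edgeR's own expression filter. That filter kept 1399 of the 12123 genes with a count. P-values were 2-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Positive log2 fold changes mean higher in ventral. The design has 2 residual degrees of freedom, and an exact test across the 3 possible splits of 4 libraries cannot go below a share of 0.333. The labels do not say that the libraries of a group came from separate pools of embryos, so p-values measure only the spread between these libraries, which may be technical. Replicate libraries differed by more than sampling noise alone gives, with a chi-square per degree of freedom of 2.61 for the ventral pair and 4.83 for the dorsal pair. Counts compressed by the ceiling do not scale with library depth. Part of these values may therefore be saturation and not variation between replicates. Replicate numbers follow the order of the samples and pair nothing.

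The genes, 18 marker lists, tests and most alternatives were fixed before the data were examined. Genes were named by 4 rules. The first took up to 12 genes per direction with the largest fold past the threshold, both libraries of a group on one side and a mean of at least 5 counts. The second took members of a list with p under 0.05 when adjusted over the list alone. The third took fixed markers of the study's question whatever their result. The fourth filled each direction up to 10 genes by unadjusted p, and those genes are said not to pass. Of the fixed markers, kdrl, flt4, ephb4a, mrc1a, efnb2a, cxcr4a, wnt5b and hbbe1.1 were matched to no row by symbol and are not analysed here.

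Lists with at least 5 tested genes were tested with camera from limma 3.58.1 on log2 CPM (counts per 1000000 gene counts) with a prior count of 2 and a preset correlation of 0.01, and with fry. Only 6 of the 18 lists reached 5 tested genes. After the data were seen, a test of summed counts was therefore added. The counts of all matched members of a list were summed per library, without the 9 genes at the ceiling, and each sum was added alone as 1 row to the edgeR fit. Its p-values were adjusted over the 18 lists. Genes stand in more than 1 list in places, and the sums of such lists are not independent. Differences between sums were given with standard errors combined as if independent.

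On simulated counts for the 1399 genes with 200 genes changed, edgeR recovered 29.9% of genes changed 2-fold and 89.1% of genes changed 4-fold, and 4.9% of its calls were false. DESeq2 1.42.0 recovered 11.2% and 53.6%, and voom 29.4% and 79.7%. In 200 simulations the list test called 88% of lists of 14 genes shifted by -0.4 and 5% of unshifted lists. The test of sums called 95.5% of sums of 20 genes changed 2-fold and 0 of 200 unshifted sums. Simulated genes varied independently of each other, and the simulated sums were fitted together. These rates therefore do not hold for lists whose members vary together, such as the immediate early and heat shock list (estimated correlation 0.23).

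Alternatives were DESeq2, voom, other scalings, other filters, robust dispersion estimates, another threshold, a block on adjacent title numbers and leaving out each library. Counts corrected for repeated identifiers, fits without the 9 genes at the ceiling, scaling to the pan-endothelial or ribosomal sums, and DESeq2 on the filtered genes were added after the data were seen. A count of 0 was read against a floor of 3 counts, the 95% limit that 0 allows. The floor equals 27.7 and 37.7 CPM in ventral libraries 1 and 2 and 25.9 and 58.4 in dorsal libraries 1 and 2. Floors and counting intervals cover counting error only.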

Results

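Endothelial cells from the ventral and the dorsal side of the posterior cardinal vein, the main vein of the embryonic trunk, were compared in zebrafish embryos at 24 hours post fertilization. The embryos carried Kaede, a fluorescent protein that light turns from green to red, under control of the endothelial gene fli1. Cells turned red on 1 side of the vein were sorted from 6 embryos per group, and 2 libraries were made per side. The title of the series places the origin of lymphatic vessels in multipotent angioblasts of the vein's floor, so the comparison asks how ventral cells differ from dorsal cells. Gene counts totalled 108405 and 79527 in ventral libraries 1 and 2, and 115876 and 51376 in dorsal libraries 1 and 2. A count was seen for 9009, 7810, 8376 and 6272 genes in the same order. Gene counts per ERCC spike-in count were 11.2 and 9.68 in the ventral libraries and 12.5 and 4.68 in the dorsal ones. Dorsal library 2 thus held the least RNA relative to the spike-ins. The most abundant spike-ins and globins lay near the ceiling, so these ratios are approximate. Across genes, log2 CPM (counts per 1000000 gene counts) correlated at 0.919 between the ventral libraries, 0.891 between the dorsal libraries and 0.862 to 0.899 between libraries of different sides.

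Endothelial transcripts were more abundant in the ventral libraries. Summed over 25 pan-endothelial genes, counts rose 2.65-fold in the ventral libraries, from 534 ± 71.2 to 1400 ± 94.6 CPM (SD, n = 2 libraries each). The sum had a log2 fold of 1.41 ± 0.21 (SE) and an adjusted p of 0.000639 over 18 lists in edgeR's quasi-likelihood test. Sums of venous, lymphatic, arterial and Notch, and mural and mesenchymal genes rose as well, by 3.83-fold, 3.35-fold, 2.75-fold and 2.78-fold. Markers of other cell types rose with them, epidermal genes by 2.98-fold and endodermal, pronephric, notochord and yolk genes by 6.84-fold, the latter on 19 counts. The epidermal sum was uneven between the ventral libraries, with 460 counts in library 1 and 129 in library 2. Both ventral libraries lay above both dorsal libraries in each of these sums. At the gene level 6 genes were higher in the ventral libraries and 0 were lower.

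The 6 genes past the threshold of edgeR's test were CD81, tpm4a, marcksl1b, TAGLN, marcksl1a and tmsb4x, with adjusted p from 0.0183 to 0.0191. CD81 (ENSDARG00000036080), a tetraspanin of the cell surface, had the largest fold, 7.8 with an interval of 4.14 to 14.7 (2 SE), at 483 ± 113 against 70.2 ± 38.3 CPM (SD, n = 2). Tropomyosin tpm4a (ENSDARG00000023963), which lines actin filaments, was 6.18-fold higher, with 42 and 34 counts in ventral and 8 and 3 in dorsal libraries. TAGLN (ENSDARG00000033466), transgelin, an actin-binding protein, was 3.89-fold higher. The actin-monomer-binding tmsb4x (ENSDARG00000077777) was 2.57-fold higher, at 2864 ± 672 against 1119 ± 69.1 CPM (SD, n = 2). The related genes marcksl1b (ENSDARG00000035715) and marcksl1a (ENSDARG00000039034), whose products bind actin and the cell membrane, were 5.04-fold and 2.9-fold higher. All 6 genes were higher in both ventral libraries than in both dorsal ones. Scaled to the pan-endothelial sum, a scaling added after the data were seen, 6 genes were higher and 1054 lower, and the median log2 fold of all genes moved to -1.45. Only CD81 and tpm4a of the 6 were then still called, and tmsb4x turned to -0.052. This scaling lowers all genes alike, so the largest folds stay and the smallest turn by construction.

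Leaving out dorsal library 1 ended all 6 calls, with adjusted p from 0.0889 to 0.144 at a median log2 fold of 2.08 against 2.15 with all libraries, and leaving out dorsal library 2 ended those of TAGLN (0.0557) and marcksl1a (0.069). DESeq2 and voom called 0 genes in either direction. At an unadjusted p under 0.05 they had 49 and 102 genes higher and 7 and 76 lower, against 105 higher and 65 lower in edgeR. Scaling to the ERCC counts also called 0, but the most abundant spike-ins lay near the ceiling, so the ERCC totals are compressed. The 6 genes had a median log2 fold of 2.20 with DESeq2, 2.09 with voom and 2.40 with ERCC scaling, against 2.15 in the edgeR test.

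**Figure D1:**
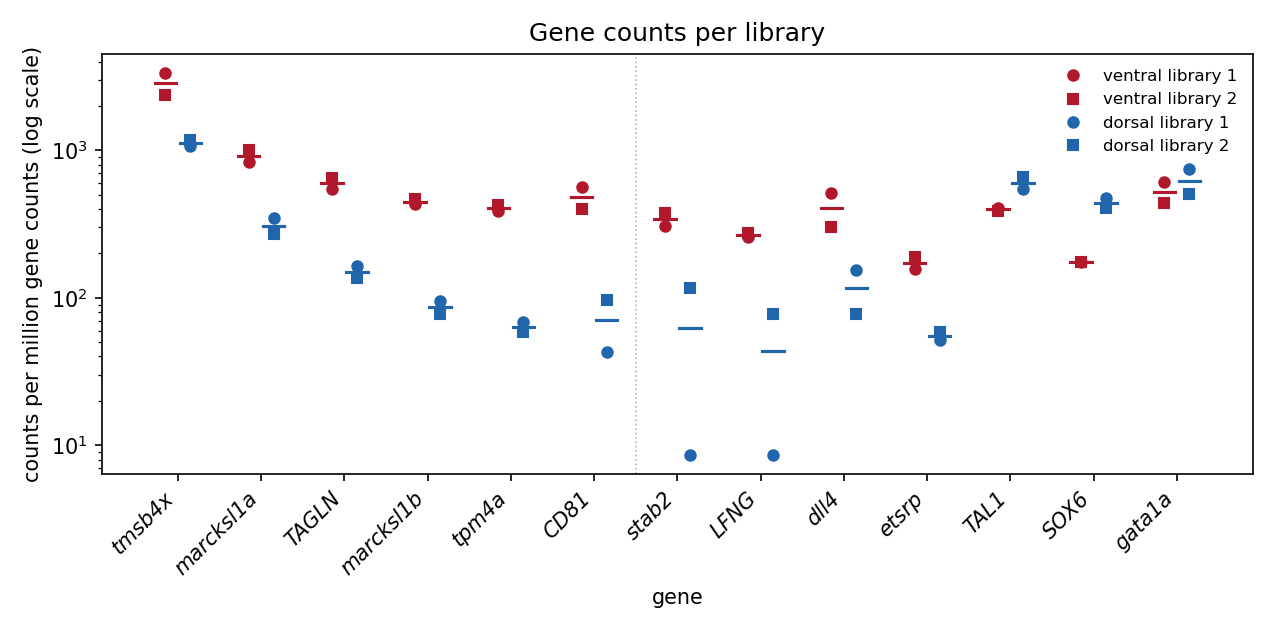
CPM (log scale) of 13 genes in each of the 4 libraries, with ventral libraries in red, dorsal libraries in blue and bars at the group means. The 6 genes left of the dotted line passed the threshold, from tmsb4x at means of 2864 against 1119 to CD81 at 483 against 70.2. Scaled to the pan-endothelial sum, which lowers all genes alike, tmsb4x turned to a log2 fold of -0.052 by construction.

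Next in line, and not past the threshold, were MIDN at a log2 fold of 2.66 ± 0.48 (SE), VAT1 at 2.94 ± 0.56, krt8 at 1.76 ± 0.33 and CFL1 at 0.80 ± 0.16, with adjusted p from 0.0527 to 0.072 in edgeR's test. CFL1 is cofilin, which severs actin filaments, and krt8 a keratin of simple epithelia. Among genes with lower values in the ventral libraries none passed. The smallest p belonged to SOX6, a transcription factor of red cell maturation, at -1.34 ± 0.30 (adjusted p = 0.106). It was followed by ELL2 at -1.28 ± 0.31, CLIC2 at -1.75 ± 0.45, h3f3a at -0.54 ± 0.15, mcl1b at -2.37 ± 0.68, TCIM at -1.31 ± 0.39 and TPR at -1.79 ± 0.54. The identifiers without a symbol ENSDARG00000075180, ENSDARG00000088449 and ENSDARG00000051887 stood at -0.53 ± 0.14, -1.23 ± 0.34 and -1.46 ± 0.42. Adjusted p for these lower genes lay between 0.106 and 0.21.

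Among the 25 pan-endothelial genes, 3 were expressed highly enough for the gene test. None of these passed over all genes, and all 3 were higher in the ventral libraries when p was adjusted over the list alone. DUSP5, a phosphatase of ERK, had a log2 fold of 1.85 ± 0.61 (SE), the adaptor gene she 1.60 ± 0.54, and plvapb, which forms diaphragms of endothelial pores, 1.22 ± 0.44. Without these 3 genes the pan-endothelial sum kept a log2 fold of 1.37 ± 0.25. Several standard markers were near the floor. The junction gene cdh5 gave 2 and 1 ventral and 4 and 0 dorsal counts, and FLI1 gave 9 and 7 against 0 and 5. The receptor gene tek gave 10 and 10 against 2 and 3, a ratio of 3.56 with a counting interval of 1.3 to 12.1. ESAM gave 9 ventral counts and 0 dorsal counts, at least 2.67-fold higher against a floor of 3 counts over the dorsal group with the ventral counts taken as exact, and with a lower counting limit of 1.76.

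Venous and lymphatic genes were more abundant in the ventral libraries. The venous sum had a log2 fold of 1.94 ± 0.28 (SE; adjusted p = 0.000639, edgeR) and the lymphatic sum 1.74 ± 0.29 (adjusted p = 0.000693). The scavenger receptor gene stab2, expressed in veins and lymphatics, stands in both lists. It gave 33 and 30 ventral and 1 and 6 dorsal counts, a log2 fold of 2.91 ± 0.70 that passed over each list alone but not over all genes (adjusted p = 0.119). With 1 venous and 2 lymphatic genes tested, adjusting over the list alone corrected for little or nothing. Without stab2 the venous sum stood at 1.70 ± 0.30 and the lymphatic sum at 1.26 ± 0.30. Without pan-endothelial members, they exceeded the pan-endothelial sum by 0.65 ± 0.40 and 0.33 ± 0.36, differences that were not resolved. NR2F2, a regulator of venous identity, gave 10 ventral counts and 1 dorsal count, a ratio of 8.9 with a counting interval of 1.27 to 386. The related stab1 gave 12 against 3, a ratio of 3.56 with an interval of 0.961 to 19.7. lyve1b gave 7 ventral counts and 0 dorsal counts, at least 2.08-fold higher against a floor of 3 counts over the dorsal group with the ventral counts taken as exact, and with a lower counting limit of 1.28, and dab2 gave 30 against 7, a ratio of 3.81 (1.64 to 10.3). PROX1, the master regulator of lymphatic fate, had 0 counts in all 4 libraries, which allows up to 8.45 CPM over all libraries. sox18 had a single count and VEGFC 4 against 2, so no difference was detectable at this depth.

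Arterial and Notch genes were also more abundant in the ventral libraries, with a log2 fold of the sum of 1.46 ± 0.27 (SE; adjusted p = 0.00122, edgeR). That sum differed from the pan-endothelial sum by 0.050 ± 0.34, so an arterial difference beyond the endothelial one was not resolved. All 3 members tested singly were higher when p was adjusted over the list alone, and none passed over all genes. These were LFNG, a modifier of Notch, at 3.07 ± 0.68, the Notch ligand gene dll4 at 1.72 ± 0.41, and the Notch target her15.1 at 1.37 ± 0.49. They held most counts of the list, and without them the sum stood at 0.69 ± 0.39 with an unadjusted p of 0.111. HEY2 gave 8 ventral and 4 dorsal counts, a ratio of 1.78 with a counting interval of 0.477 to 8.08. The venous sum without pan-endothelial members exceeded the arterial sum by 0.60 ± 0.43, an interval of -0.27 to 1.47 (2 SE), so a difference between them was not resolved.

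Angioblast genes did not pass as a group with all libraries. Their sum had a log2 fold of 0.27 ± 0.19 (SE; adjusted p = 0.309, edgeR), against 0.53 ± 0.20 without dorsal library 2 (adjusted p = 0.0485) and 0.021 ± 0.21 without dorsal library 1 (adjusted p = 0.924). By camera without a filter and with the preset correlation, the list of 12 genes with a count was higher as a whole (adjusted p = 0.00136). Not all of its members were higher, with TAL1 at -0.54 in the fit without a filter, and those below the filter had few counts. The early endothelial regulator etsrp, also called etv2, stood at 1.66 ± 0.54, with 17 and 15 ventral and 6 and 3 dorsal counts, and passed when adjusted over the list alone but not over all genes (adjusted p = 0.255). TAL1, active in both blood and vessel precursors, stood at -0.59 ± 0.26 and LMO2, its partner, at 0.39 ± 0.33, and neither passed. Without TAL1, LMO2 and GATA2 the sum stood at 1.25 ± 0.29, but these 3 were chosen after their values were seen and had the lowest folds of the tested members, so that sum tests nothing. The blood stem cell gene RUNX1 had 0 counts in all libraries and MYB gave 7 and 4 against 8 and 5.

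Immediate early and heat shock genes were higher in the ventral libraries as a list by camera (adjusted p = 0.000279), with 9 of 11 tested members above 0. The call was lost with an estimated correlation, at an adjusted p = 0.373, and with fry, at an adjusted p = 0.257. Over the list alone 6 members passed, and none over all genes. These were the AP-1 genes JUNB at a log2 fold of 1.63 ± 0.37 (SE), FOSL2 at 1.51 ± 0.42 and FOS at 1.02 ± 0.31, the antiproliferative genes BTG1 at 1.02 ± 0.36 and BTG2 at 0.83 ± 0.29, and DUSP5. The abundant chaperone HSPA8 stood at -0.16 ± 0.20, and the sum of the whole list, in which HSPA8 has the most counts, at 0.29 ± 0.22 (adjusted p = 0.333, edgeR). Without dorsal library 2 that sum stood at 0.61 ± 0.14 (adjusted p = 0.00584) and without dorsal library 1 at 0.038 ± 0.14 (adjusted p = 0.845). Scaled to the pan-endothelial sum, which lowers all genes alike, FOS, BTG1 and BTG2 turned to -0.43, -0.40 and -0.57 by construction.

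Globin transcripts were among the most abundant in all libraries. The 9 genes near the ceiling of identifiers, 6 globins and 3 genes without a symbol, held 8.47% and 11.3% of gene counts in ventral and 7.93% and 17.2% in dorsal libraries. These shares are too low, since the genes are saturated. A correction for repeated identifiers, chosen after the data were seen and unreliable this close to the ceiling, gave 32.4% and 33% in ventral and 31.6% and 41% in dorsal libraries. The pan-endothelial sum was 0.147% and 0.133% of ventral and 0.0483% and 0.0584% of dorsal gene counts. Of 14 erythroid genes tested, 3 were globins at the ceiling, whose folds reflect library scaling alone. Of the other 11, 9 had a log2 fold below 0, and none passed, over all genes or over the list alone. The list of 14 gave an adjusted p of 0.0573 by camera, 0.0552 without the genes at the ceiling, and 0.0273 to 0.373 over all alternatives. SPTB, a spectrin of the red cell membrane, stood at -0.61 ± 0.20 (SE), the globin regulator klf1 at -0.59 ± 0.25 and gata1a at -0.27 ± 0.25. The sum of the 11 members below the ceiling had a log2 fold of -0.27 ± 0.22 (adjusted p = 0.333, edgeR), with -0.40 ± 0.12 without dorsal library 2 (adjusted p = 0.0167) and -0.069 ± 0.13 without dorsal library 1 (adjusted p = 0.746). In the cell cycle list 13 of 18 tested genes were below 0, among them PCNA at -0.42 ± 0.21 and TOP2A at -0.95 ± 0.50, and none passed. That list gave an adjusted p of 0.112 by camera and 0.00754 to 0.692 over all alternatives. Its sum stood at -0.32 ± 0.20 (adjusted p = 0.242, edgeR). That sum stood at -0.36 ± 0.15 without dorsal library 2, -0.23 ± 0.16 without dorsal library 1, -0.18 ± 0.45 without ventral library 1 and -0.45 ± 0.41 without ventral library 2.

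Signal pathway sums lay close to the threshold. Wnt genes had a log2 fold of 0.94 ± 0.34 (SE) and BMP and TGF-beta genes 0.78 ± 0.28, both with an adjusted p of 0.0432 in edgeR's test. ID1, a target of BMP signalling, stood at 1.46 ± 0.48 and was the single tested member of its list, and CTNNB1, which encodes beta-catenin, stood at 0.81 ± 0.47. With the 18 sums fitted together both lists missed the threshold (adjusted p = 0.0528), and without dorsal library 1 both stood at an adjusted p of 0.355. Without ventral library 1 they stood at adjusted p of 0.0936 and 0.203.

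Markers of other cell types differed between single libraries. Epidermal genes had a summed log2 fold of 1.58 ± 0.43 (SE; adjusted p = 0.0135, edgeR), but 9 of the 20 list members were counted in ventral library 1 alone, with 186 counts, among them krt4 with 58 and cyt1l with 65. Without ventral library 1 the sum stood at 0.68 ± 0.25 (adjusted p = 0.0166), and without dorsal library 1 the call ended, at 1.1 ± 0.50 (adjusted p = 0.153). Over the list alone krt8, krt18a.1 and pfn1 passed, at 1.76 ± 0.33, 1.87 ± 0.39 and 1.29 ± 0.45, and without these 3 the sum stood at 1.54 ± 0.73 with all libraries and at -0.35 ± 0.36 without ventral library 1. By camera the list gave an adjusted p of 0.0573, and 0.373 with an estimated correlation. In the mural and mesenchymal sum (log2 fold 1.48 ± 0.25, adjusted p = 0.000693) TAGLN was the leading gene, and twist1b was counted 26 times in ventral library 1 and 1 time in all others. Without TAGLN that sum stood at 1.11 ± 0.42, and at 0.33 ± 0.41 without ventral library 1 as well. The neutrophil gene lyz gave 17 counts in dorsal library 2 and 3 in the others together, and the myeloid and haematopoietic sum stood at -0.41 ± 0.60 (adjusted p = 0.611, edgeR). Its sign depended on single libraries, at -1.29 ± 0.37 without dorsal library 1 (adjusted p = 0.0211), -0.97 ± 0.34 without ventral library 1 (0.0136) and 1.07 ± 0.42 without dorsal library 2 (0.0492).

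Endodermal, pronephric, notochord and yolk genes gave 17 ventral and 2 dorsal counts in all, a log2 fold of 2.77 ± 0.87 (SE; adjusted p = 0.0261, edgeR), and the call ended whichever library was left out, with log2 folds from 2.0 ± 1.57 to 3.33 ± 1.43 and adjusted p from 0.0544 to 0.355. Skeletal muscle genes (-0.91 ± 1.0) and neural genes (0.14 ± 0.47) did not pass. Ribosomal protein genes (0.0039 ± 0.35) and mitochondrially encoded genes (0.045 ± 0.35) differed by less than their errors, and camera gave adjusted p of 0.909 and 0.6. Without dorsal library 2 the mitochondrial sum stood at 0.34 ± 0.14 (adjusted p = 0.0492, edgeR) and without dorsal library 1 at -0.17 ± 0.15.

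**Figure D2:**
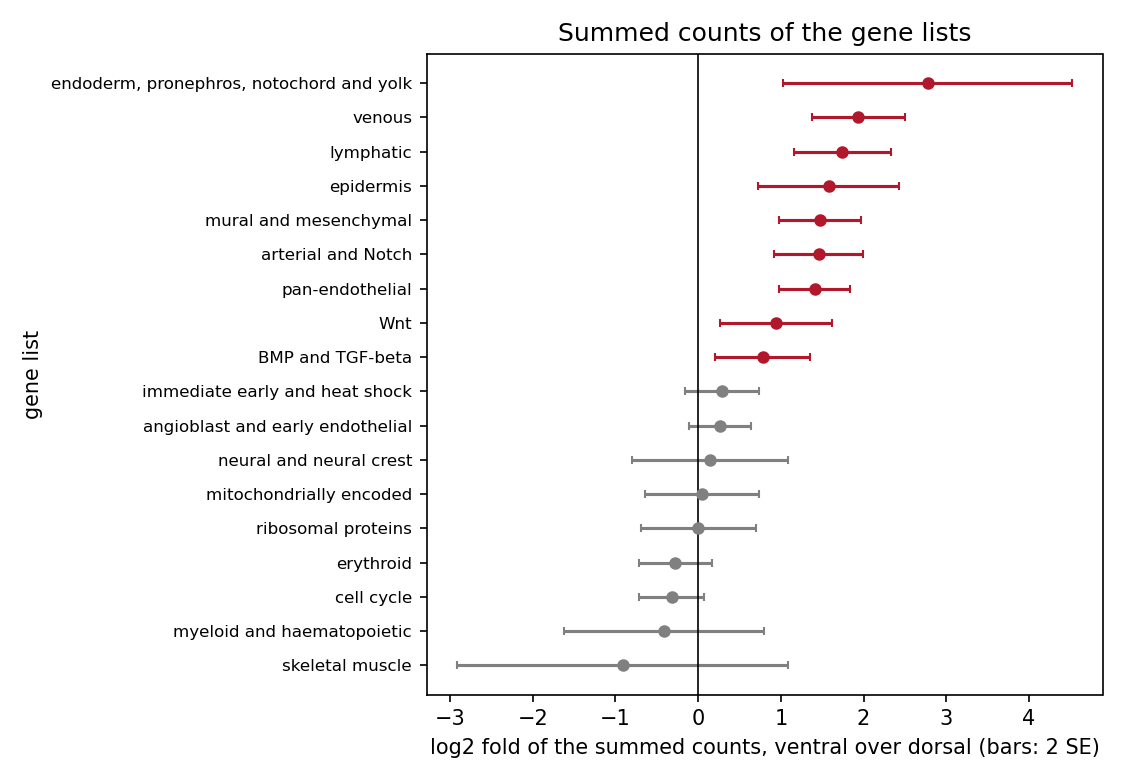
Log2 fold of the summed counts of 18 gene lists, ventral over dorsal, with bars of 2 SE. Red marks the 9 lists with an adjusted p under 0.05, from BMP and TGF-beta at 0.78 to endoderm, pronephros, notochord and yolk at 2.77, the latter on 19 counts.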

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

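Reads outside annotated genes lay beyond the gene counts. They made up 27.2% and 24.6% of the column total in ventral libraries 1 and 2, and 24.4% and 19.5% in dorsal libraries 1 and 2. These rows were read as read counts, an inference from their size, and the column total then mixes reads with identifier counts. Positions of the reads were not analysed here. Unaligned reads made up 69.2% and 71.4% of the column total in ventral libraries 1 and 2, and 71.7% and 77.7% in dorsal libraries 1 and 2. The share outside genes depends on the unaligned share, so its differences between libraries were not read as a signal. Groups of 2 libraries are too small for a test of single outlying libraries.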

How the results depend on the processing

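The alternatives with corrected counts, without genes at the ceiling, with pan-endothelial or ribosomal scaling, with DESeq2 on the filtered genes, and all tests of sums were chosen after the data were seen. Of 39 named genes tested, 30 kept their direction under all alternatives run. The other 9 reversed only when scaled to the pan-endothelial sum, which lowers all genes alike, so that small positive folds turn by construction and the reversals test nothing about single genes: tmsb4x -0.052, plvapb -0.21, her15.1 -0.11, pfn1 -0.12, FOS -0.43, BTG1 -0.40, BTG2 -0.57, LMO2 -1.05 and CFL1 -0.62. The 6 genes higher in ventral became 0 with DESeq2 (on 12123 or 1399 genes), voom and ERCC scaling, which moved the median log2 fold of all genes to 0.22. They became 14 with total counts, 43 without a filter, 37 with robust dispersion, 21 with corrected counts, 18 without the genes at the ceiling and 12 at an adjusted p under 0.1. Leaving out 1 library gave 0 to 46 higher and 1 to 5 lower genes, with 0 higher without dorsal library 1 and 46 without ventral library 2, and the lone library is then assumed to vary like the other group. The 0 lower genes became 4 without a filter, 4 with robust dispersion, 1 with corrected counts and 1054 with pan-endothelial scaling. The 1 list past camera's threshold became 0 with an estimated correlation, 0 with fry, 2 with ranks, 10 without a filter, 3 with the 10-count filter and 0 to 3 with 1 library left out, 0 being without dorsal library 1. The 9 sums past the threshold became 0 with ERCC scaling, where the pan-endothelial sum stood at 1.74 ± 1.2 against 1.41 ± 0.21, 7 when fitted together and 6 to 14 with 1 library left out. Within-group correlation exceeded that between groups by 0.026, and by 0.057 with Spearman's measure. No paired analysis was possible from replicate numbers, because the labels give the groups none in common. A block on adjacent title numbers, a pairing the labels do not state, gave 10 higher genes, the 6 among them, and 3 lists. Apart from pan-endothelial scaling, the cause was not tested. Depth limits most vessel markers, which had under 10 counts per library.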

Other observations

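The genes of this paragraph were chosen after their values were seen, and none passed the threshold. The endothelial adhesion gene MCAM had a log2 fold of 1.86 ± 0.45 (SE), with 29 and 21 ventral and 7 and 5 dorsal counts. The endothelial receptor gene GPR182 stood at 2.77 ± 0.75, with 12 and 12 against 2 and 1 counts. DUSP6, a target and inhibitor of ERK signalling, stood at 1.87 ± 0.42, and her12, a hairy-related transcription factor gene, at 2.04 ± 0.48. The beta-actin genes actb1 and actb2 stood at 0.65 ± 0.15 and 0.73 ± 0.18, the calponin CNN2 at 2.38 ± 0.52 and the actin linker MSN at 0.84 ± 0.23.

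SALL4, a transcription factor gene of stem and progenitor cells, had 268 counts in ventral library 1 and 26, 14 and 9 in ventral library 2 and dorsal libraries 1 and 2 (log2 fold 3.35 ± 0.81, adjusted p = 0.12 in edgeR). Genes with at least 10 counts in 1 library and 0 in all others numbered 7 in ventral library 1, among them cyt1l, krt4, krt17 and cldni, and 1 in ventral library 2, slco2b1 with 26 counts. Dorsal libraries had 0 such genes.

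Of the tests below, those of the ceiling and of the heat shock genes were set before their results were seen, and the others after. The prediction set for the endothelial share asked for a pan-endothelial sum past its test and an erythroid sum below 0. It also asked for the median of the 6 called genes to lie within 2 SE of the pan-endothelial sum. Each of these parts was met. The demand that the erythroid sum pass its own test was added after its value was seen. The first pattern is the 6 genes higher in the ventral libraries. For the ceiling, 6 of 6 were still called with corrected counts, but the correction raises larger counts the most. Keeping the calls of genes far below the ceiling was thus largely fixed in advance and decides little. For low depth of dorsal library 2, 6 of 6 had a log2 fold of at least 1 without that library, although the calls of TAGLN and marcksl1a ended. The 6 genes were picked in a fit that includes dorsal library 1. Keeping their folds against that library was thus also largely fixed in advance and decides little. A smaller share of endothelial RNA in the dorsal libraries may account for the pattern. The median of the 6 genes lay above the pan-endothelial sum by 0.74 ± 0.38 (SE), under 2 SE. Part of that SE is the spread of folds among the 6 genes, treated as replicates, and not error between libraries. Lying under 2 SE therefore decides little. CD81 and tpm4a lay above the pan-endothelial sum by 1.56 ± 0.50 and 1.22 ± 0.44. Both were still called when scaled to that sum (adjusted p = 0.0137 and 0.0485, edgeR). marcksl1b also lay above it by more than 2 SE, at 0.93 ± 0.41, but was not called when scaled to it (0.90, adjusted p = 0.112, edgeR). These genes have the largest folds of the 6, and the scaling ignores the error of the sum, so their values do not argue against the share. For all 6 genes the share cannot be told apart from a difference between ventral and dorsal cells. The erythroid sum, at -0.27 ± 0.22, did not pass its test with all libraries and stood at -0.40 ± 0.12 without dorsal library 2. Many endothelial markers had few counts, and the epidermal sum exceeded the erythroid sum by 1.85 ± 0.48, partly through 1 library. Whether chance gave the 6 calls cannot be settled by regrouping, since 1 of the 3 splits into pairs, the real one, called 6 genes and the highest other 0, and 3 splits are too few for a share under 0.05.

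The second pattern is the higher immediate early genes of the ventral libraries. Their sum, without heat shock and pan-endothelial members, had a log2 fold of 0.95 ± 0.20 (SE) and lay below the pan-endothelial sum by a difference of -0.46 ± 0.29. A smaller endothelial share in the dorsal libraries could therefore give this pattern too, and it stays open for the reasons given for TAGLN, marcksl1a and tmsb4x. Stronger handling stress of the ventral samples cannot be told apart from it, because the 5 heat shock members, at -0.014 ± 0.93, had too few counts. A ventral and dorsal difference in signalling between the cells remains untested.

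The third pattern is the higher arterial and Notch sum in cells of a vein. It differed from the pan-endothelial sum by 0.050 ± 0.34 (SE), so the same difference in endothelial share may carry it. Within this list dll4, LFNG and her15.1 held most counts, and a Notch difference specific to these 3 genes was not tested apart from the endothelial share.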
